A study of Mus musculus with 22 samples.

How the data were processed

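Total RNA from mouse spinal cord above T6 (rostral) and below T6 (caudal) had been hybridised to 22 Affymetrix Mouse430_2 arrays. The values deposited by the authors are on a log2 scale, made with RMA per the submitters' processing notes, which give no version of the tool. They were used as they are. The file holds 45101 probe sets. Of these, 64 are controls, 34945 carry 1 gene symbol in the platform annotation, 932 several and 9160 none listed; only those with 1 symbol were used as genes. No symbol needed an update from the RefSeq gene table. Where a gene had several probe sets, the one with the highest mean over the grouped arrays was taken, which gave 18193 genes, and a gene's other probe sets were checked for the sign of the change.

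Samples were grouped by the treatment, time and region in their labels. The rostral array 276 was left out of the groups because its description gives 48 h and its source name 24 h, and it was counted as either only in alternatives. The labels do not say that the arrays of a group are separate animals, so the p-values measure the spread between these samples. The numbers in the titles were not taken as pairs in the reported fit. They run in blocks, 271 to 274 for 48 h, 277 to 280 for sham and 281 to 283 for 24 h. An effect tied to the order of the numbers thus cannot be told apart from treatment and time.

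A model with a mean for each of 6 groups was fitted to 21 arrays with limma 3.58.1 (lmFit and eBayes, R 4.3.3, statmod 1.5.0). Contrasts compared clamp with sham, 48 h with 24 h and caudal with rostral, and took the difference between regions in the clamp effect. The spread was pooled over all groups (18.7 degrees of freedom with the prior). Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, in either direction, and each contrast was adjusted on its own. All tests were two-sided. The counts adjusted over a list alone apply the same adjustment to the measured members of that list.

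The groups, the contrasts, 37 gene lists, the rule for named genes and most alternatives were set before the data were examined. The rule named, among genes past the adjusted p whose arrays do not overlap between the groups (for differences of effects, past the adjusted p alone), the 10 largest rises and the 10 largest falls. It added up to 4 members with the smallest p of each list and all Hox genes in the sham comparison. Where under 5 genes passed, it named these and the 3 smallest p-values as values. Clone, RIKEN and predicted names were counted but not named. The lists cover homeostatic microglia, monocytes and macrophages, neutrophils, T and B lymphocytes, reactive and homeostatic astrocytes, pan-neuronal genes, motor, inhibitory and excitatory neurons, myelin and oligodendrocytes, their precursors, endothelial cells, mural cells and fibroblasts, Schwann cells, erythroid cells, skeletal muscle, chemokines, cytokines with NF-kappaB targets, interferon response, complement, antigen presentation, heat shock, unfolded protein response, hypoxia and glycolysis, oxidative stress, p53 targets, cell cycle, immediate early genes, axon injury, extracellular matrix, cholesterol synthesis, glutamate receptors, glucocorticoid response, circadian clock, and rostral and caudal Hox genes. Another 3 lists (cardiac muscle, adipocytes, sensory ganglia) were made after the data had been seen and were tested as a family of their own.

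Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 37 lists of a contrast, and again with a correlation estimated for each list. Further alternatives were fry (directional and mixed), the mean of a gene's probe sets, every probe set as its own feature, the brighter genes only, quantile normalisation repeated, arrays centred on their median, eBayes with trend and robust, array weights, a fit of the compared groups alone, a change of at least 2-fold, the number in the title as a random or fixed block, array 276 as 24 h or 48 h, and each array left out in turn. Camera takes no block, so the blocked list test used cameraPR on the z-scores of the fit, set against cameraPR without the block. Alternatives added after seeing the data were leaving out both arrays numbered 283, caudal arrays 271, 274 and 280, or all 5 of these, leaving out muscle and adipocyte genes, the fixed block for the differences of effects, cameraPR without a block, the lists without both arrays numbered 283 and without each array in turn, the correlation within a number without the arrays numbered 283, and the region check with the mean of probe sets, with quantile normalisation repeated and with arrays centred.

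No read depth exists for arrays. The medians of the log2 values were, for caudal arrays, 6.79 (271), 6.88 (272), 6.86 (273), 6.83 (274), 6.85 (278), 6.88 (279), 6.86 (280), 6.85 (281), 6.87 (282) and 6.85 (283), and for rostral arrays 6.86 (271), 6.87 (272), 6.85 (273), 6.85 (274), 6.84 (276), 6.85 (277), 6.84 (278), 6.84 (279), 6.85 (280), 6.85 (281), 6.87 (282) and 6.86 (283). No pair of arrays held identical values. The number of arrays limits the precision. The steps were tested on simulated data with the same groups, in which 50 genes changed by a log2 value of 1 in each contrast. Between 30 (effect difference at 24 h) and 47 (rostral clamp against sham at 48 h) of them were called. A list shifted by 1 was the only list of 37 that camera called. Genes were drawn independently and with the same spread in every group. The simulation thus does not show how camera behaves with correlated genes, or how many genes are recovered where spreads differ between groups.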

Results

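Gene expression was measured with Affymetrix Mouse430_2 arrays in the spinal cord of C57Bl/6 wild-type mice after the aorta had been clamped for 7.5 min, or after a sham operation. Cord from above T6 (rostral) and from below T6 (caudal) was hybridised to separate arrays. The comparisons ask which transcripts differ after clamping at 24 h and at 48 h, and whether the response above T6 differs from that below it. There were 4 sham rostral, 3 sham caudal, 3 rostral and 3 caudal 24 h, and 4 rostral and 4 caudal 48 h arrays. The remaining rostral array, 276, carried both 24 h and 48 h in its labels and was in no group. Values are log2 RMA signals made by the authors, and the median of an array lay between 6.79 and 6.88 on all 22 arrays. After the genes listed for each probe set were collapsed, 18193 genes were tested with limma. Adjusted p-values are Benjamini-Hochberg values over these genes, errors of changes are standard errors (SE), and n is the number of arrays. Counts expected by chance assume that the spread pooled over all groups holds in the groups compared. The number of arrays limits the precision of every value.

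Some arrays stood apart from the others, and these facts stand beside the results that follow. The caudal 48 h array 271 had a standard deviation over probe sets of 2.05, against 2.21 to 2.27 on the other 21 arrays, and its median correlation with the other arrays was 0.903. The 5-prime signal of the Gapdh control was below the 3-prime signal, with a difference of −1.05, on caudal 48 h array 274 and −0.68 on sham caudal array 280. It lay between −0.21 and 0.04 on the other 20 arrays. Transcripts of heart muscle were raised on the rostral and on most caudal 48 h arrays. The median rise of 40 cardiac genes over the sham mean of the region was 1.65, 3.12, 3.25 and 2.30 on rostral arrays 271 to 274 and 1.41, 0.54, 0.13 and 0.56 on caudal arrays 271 to 274. It lay between −0.01 and 0.21 on the 24 h arrays. The cardiac list was made after the data had been seen. Both arrays numbered 283 (24 h) had region genes that went against their region labels.

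Sham arrays were compared between regions to see which transcripts mark the samples from below T6. Hoxd10, a transcription factor gene of posterior body identity, had a log2 signal of 9.37 ± 0.06 (SD, n = 3) in caudal and 4.34 ± 0.26 (SD, n = 4) in rostral cord, a log2 difference of 5.03 ± 1.05 (SE, adjusted p = 0.0431). Hoxd9 was higher by 2.70 ± 0.52 (adjusted p = 0.0245), and Hoxc5, of more anterior identity, was lower, with a difference of −2.18 ± 0.46 (adjusted p = 0.0431). These errors use the spread pooled over all 6 groups, including the arrays numbered 283, and not the spread of the sham arrays alone. Without both arrays numbered 283 the limma adjusted p was 1.38e-09 for Hoxd10, 3.35e-08 for Hoxd9 and 2.12e-08 for Hoxc5. Transcripts of sensory ganglia and peripheral nerve were also higher in caudal samples. Among them, Scn11a, a sodium channel of pain-sensing neurons, differed by 2.78 ± 0.53 (adjusted p = 0.024), Pirt by 2.63 ± 0.44, and Pmp2, a peripheral myelin protein, by 2.59 ± 0.43. Egr2, a regulator of Schwann cell myelination, differed by 2.35 ± 0.43. Mlip (2.67 ± 0.39), Fxyd2 (2.53 ± 0.53), Sbspon (2.51 ± 0.45) and Aqp1, a water channel (2.44 ± 0.36), completed the 10 largest rises. Another probe set of Fxyd2 and of Mlip had the opposite sign. For these 11 genes no caudal sham array overlapped a rostral one, which the naming rule required. The largest rises and falls named here and below against sham, over time or between regions are the largest among such genes. In all, 61 of 18193 genes passed, 60 higher and 1 lower in caudal cord, and Hoxc5 was the lower one.

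The lists of region and cell type genes moved in the same comparison. Of 11 caudal Hox genes, 4 were higher (Hoxd10, Hoxd9, Hoxb13 by 0.78 and Hoxc13 by 0.81), against 8 adjusted over the list alone; camera gave the list an adjusted p of 2.37e-15 and 0.021 with an estimated correlation. Hoxc10 had 10.29 ± 0.17 (SD, n = 3) in caudal and 5.86 ± 0.38 (SD, n = 4) in rostral cord and did not pass (4.43 ± 0.96, adjusted p = 0.0537), and neither did Hoxa10 (3.02) or Hoxa11 (1.0). Hoxd11 (0.81), Hoxd12 (0.09), Hoxa13 (−0.10) and Hoxd13 (−0.08) did not pass either. Of 8 rostral Hox genes, 1 was lower over all genes and 7 adjusted over the list alone (median −0.57, camera adjusted p = 1.26e-11, and 0.0274 with an estimated correlation). Hoxa4 (−0.90), Hoxc4 (−0.81) and Hoxa5 (−0.63) did not pass over all genes. Schwann cell genes were higher in caudal samples, 3 of 7 measured (Pmp2, Egr2 and Ncmap, by 1.52 ± 0.28), 5 adjusted over the list alone, with a median of 1.52 (camera adjusted p = 8.1e-12, and 0.021 with an estimated correlation). A sensory ganglion list made after the data had been seen had 5 of 8 genes higher and 8 adjusted over the list alone (median 1.39, camera adjusted p = 3.19e-22, and 0.00148 with an estimated correlation); Isl1, by 0.92 ± 0.18, also belongs to motor neurons. Mural cell and fibroblast genes had 0 of 10 passing with limma over all genes and 5 adjusted over the list alone (median 0.60, camera adjusted p = 1.07e-06, and 0.0221 with an estimated correlation). In this comparison 1003 genes had an unadjusted p under 0.05, against 910 expected by chance. The 910 assumes that the pooled spread holds in sham, so a count near it does not show that few genes differ. Calls for neutrophils (1.02), extracellular matrix, antigen presentation, axon injury genes and homeostatic microglia ended with an estimated correlation (adjusted p between 0.224 and 0.558). With an estimated correlation the Schwann cell, caudal Hox and mural cell calls ended without caudal array 279 (adjusted p = 0.0608 for each), and the rostral Hox call without caudal array 278 (0.0512) or 279 (0.0833). Each array decided the count of 61: it was 14, 19, 18 and 25 without rostral array 277, 278, 279 or 280, and 0, 0 and 24 without caudal array 278, 279 or 280. It was 98 without both arrays numbered 283, 832 in a fit of sham arrays alone, 1257 with array weights and 0 with limma among the brighter genes. With the number in the title as a fixed block, limma also called 0 genes, though whether the numbers mark pairs stays open. Without both arrays numbered 283 Hoxc10 passed (adjusted p = 6.88e-09), as did Hoxa10, Hoxa11, Hoxd11, Hoxa4 and Hoxc4.

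These 61 genes, among them genes of sensory ganglia and peripheral nerve, place each array between the sham means of rostral (0) and caudal (1) samples. The sham caudal arrays had median positions of 0.970 to 1.06, and the rostral arrays other than 283 of −0.0711 to 0.0961. The array labelled caudal 283 lay at 0.104, with 60 of 61 genes nearer the rostral mean, and the array labelled rostral 283 at 0.633, with 50 of 61 nearer the caudal mean. Hoxc10 was 5.67 on the array labelled caudal 283 and 10.14 on that labelled rostral 283, while the other 9 caudal arrays had 9.19 to 10.48 and the other 10 rostral arrays 5.32 to 6.22. Hoxc5 went the other way, with 8.22 and 6.07. Among the other clamped caudal arrays, 271 lay at 0.488, 282 at 0.548 and the rest at 0.684 to 0.787. Both arrays were kept under their labels in the comparisons, so every 24 h result below mixes them with arrays whose region genes match their labels.

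**Figure D1:**
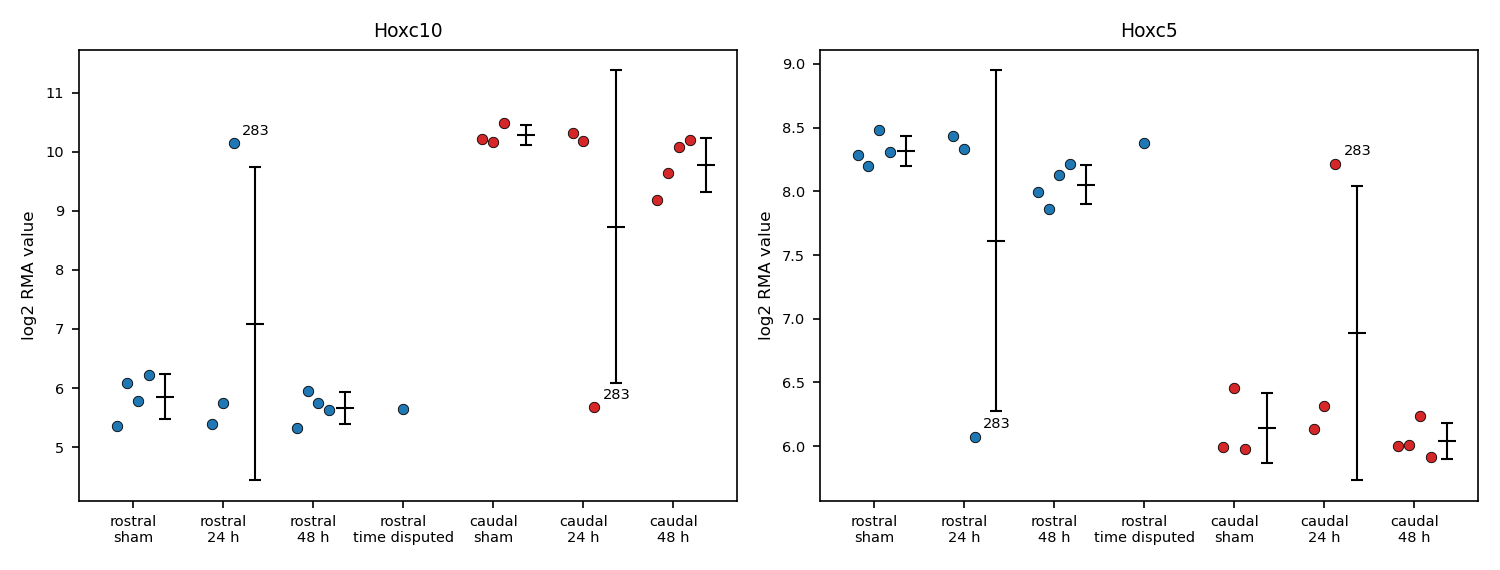
Log2 RMA signal of Hoxc10 and Hoxc5 on each array (points), by region and time, with bars for the mean ± SD of a group. The array labelled caudal 283 had Hoxc10 at 5.67 and that labelled rostral 283 at 10.14, against 9.19 to 10.48 on the other caudal and 5.32 to 6.22 on the other rostral arrays of the groups.

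The response below T6 was measured by comparing caudal cord 48 h after clamping with caudal sham. Cytokine and chemokine transcripts had the largest measured rises. Il6, an inflammatory cytokine, went from 3.95 ± 0.07 (SD, n = 3) to 11.09 ± 1.32 (SD, n = 4), a log2 change of 7.14 ± 0.81 (SE, adjusted p = 3.55e-05). The chemokine genes Ccl3 (6.72 ± 0.84), Cxcl10 (6.50 ± 0.80), Ccl2 (5.79 ± 0.75), Cxcl2 (5.47 ± 0.62) and Ccl12 (5.41 ± 0.72) followed, with Ptx3 (4.98 ± 0.72, and 0.20 for another probe set), the cytokine signalling inhibitor Socs3 (4.96 ± 0.79), and the interferon-induced Rsad2 (4.89 ± 0.70) and Ifit1 (4.81 ± 0.67). The sham signals of Il6, Ccl3 (4.40) and Cxcl2 (3.82) lay below the lower quartile of every array (5.17 to 5.52), so signal over background limits the size of their changes and the order among the largest. The largest falls were in Gpr17, a receptor of the oligodendrocyte lineage (−1.66 ± 0.28, from 9.27 ± 0.16 to 7.62 ± 0.59), Depdc7 (−1.64 ± 0.36), Sox2ot (−1.56 ± 0.34), Tek, the endothelial angiopoietin receptor (−1.53 ± 0.30), Psd2 (−1.51), Trim59 (−1.51), Slco1c1, a blood-brain barrier transporter (−1.47 ± 0.31), Myorg (−1.47), Dlgap2 (−1.46) and Slc26a7 (−1.42, with another probe set of opposite sign). As the naming rule required, for these 20 genes no 48 h array overlapped a sham one. In all, 2279 genes passed, 1004 higher and 1275 lower, and 468 and 75 of them changed at least 2-fold. With each array centred on its median the larger share turned, to 1087 higher and 975 lower.

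Inflammatory lists rose in caudal cord at 48 h. Interferon response genes rose in 12 of 12, with a median of 3.35 (Usp18 4.48, Irf7 3.38, Ifit2 3.37). Of 15 chemokine genes 13 rose (15 adjusted over the list alone, median 3.58; Ccl4 3.99 ± 0.44), and of 18 cytokine, adhesion and NF-kappaB target genes 16 rose (17 adjusted over the list alone, median 2.53; Tlr2 3.39 ± 0.33, Il1a 3.21, Nfkbiz 2.28). Monocyte and macrophage genes rose in 10 of 15 (13 adjusted over the list alone, median 1.81), including Cd14 (4.54 ± 0.49), Fcgr1 (2.79 ± 0.27) and Cybb (2.50). Reactive astrocyte genes rose in 11 of 13 (11 adjusted over the list alone, median 1.77), such as Timp1 (3.88 ± 0.61), Hspb1 (2.32) and Aspg (2.09). Complement genes rose in 7 of 10 (7 adjusted over the list alone, median 1.13; C3ar1 2.47, C1qb 1.86, C1qc 1.59 ± 0.15), and antigen presentation genes rose in 7 and fell in 2 of 13 (8 and 4 adjusted over the list alone, median 0.87; Nlrc5 2.80, Tap1 2.63). Camera called all 7 lists up, with adjusted p-values from 1.71e-17 to 0.00194. None of these calls held with an estimated correlation, where the adjusted p was 0.0672 for chemokines, cytokines and monocytes, 0.0766 for interferon response, 0.104 for complement, 0.132 for reactive astrocytes and 0.163 for antigen presentation.

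Stress and cell death lists also moved. Immediate early genes rose in 8 of 10 (8 adjusted over the list alone, median 1.56; Junb 3.25, Fos 2.62, Ier2 1.99). Targets of p53 rose in 8 of 11 (8 adjusted over the list alone, median 0.71; Fas 1.53, Gadd45a 1.36, Casp8 1.16). Cell cycle genes rose in 6 of 17 (10 adjusted over the list alone, median 0.41; Cdk1 1.47, Birc5 1.07), axon injury genes in 4 of 11 (5 adjusted over the list alone, median 0.46; Atf3 3.62 ± 0.37), and unfolded protein response genes in 4 of 12 (6 higher and 1 lower adjusted over the list alone, median 0.39; Atf4 0.66). Oxidative stress genes rose in 3 of 11 (5 adjusted over the list alone, median 0.50; Hmox1 2.72, Srxn1 1.36) and glucocorticoid response genes in 4 of 10 (5 adjusted over the list alone, median 0.84; Plin4 2.85, Pdk4 1.61, Fkbp5 1.60). Camera called these 7 lists up (adjusted p from 3.4e-10 to 0.00395), and none held with an estimated correlation (adjusted p from 0.0672 to 0.198). Heat shock genes rose in 3 of 11 (Hspa1b 2.18, Hspa1a 1.89) without a call for the list (camera adjusted p = 0.0856).

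Lists of vessel, neuron and oligodendrocyte genes fell. Endothelial and tight junction genes fell in 7 of 13 (1 higher and 7 lower adjusted over the list alone, median −0.51), including the transporters Abcb1a (−1.05) and Slco1a4 (−1.01 ± 0.20). Oligodendrocyte precursor genes fell in 3 of 8 (4 adjusted over the list alone, median −0.51; Olig2 −0.95, Cspg4 −0.48), and myelin genes in 2 of 11 (2 adjusted over the list alone, median −0.21; Aspa −1.21, Ugt8a −0.95). Motor neuron genes fell in 3 of 10 (6 adjusted over the list alone, median −0.46; Chodl −1.21, Prph −0.60, Ret −0.52), pan-neuronal genes in 2 of 12 (6 adjusted over the list alone, median −0.41; Map2 −0.40 ± 0.13, Nefl −0.31 ± 0.10), and glutamate receptor genes in 1 of 10 (5 adjusted over the list alone, median −0.46; Grik1 −0.79). Camera called these 6 lists down, with adjusted p-values from 0.000742 to 0.038. With an estimated correlation none was called, with adjusted p-values from 0.117 for motor neurons to 0.361 for pan-neuronal genes. Array 271 carried much of the neuronal falls: its pan-neuronal mean was 11.50, against 12.33 to 12.51 on the other 48 h arrays and 12.60 to 12.66 in sham. Without it the medians were −0.18 for pan-neuronal and −0.28 for motor neuron genes, the medians of oligodendrocyte precursor (−0.45) and endothelial genes (−0.47) changed little, and the calls for myelin and glutamate receptor genes ended (camera adjusted p = 0.228 and 0.059). Map2, Nefl and Cspg4 lost their calls when each array was centred on its median.

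The remaining 17 lists were not called in caudal cord at 48 h (camera adjusted p from 0.0542 to 0.787). Of homeostatic microglia genes 2 rose and 1 fell of 12 (Fcrls 1.91 ± 0.17, Olfml3 0.57, Sall1 −0.62), of homeostatic astrocyte genes 1 rose (Sox9 0.51) and 1 fell (Fgfr3 −0.80) of 12, and of hypoxia and glycolysis genes 3 rose (Hk2 1.12, Adm 0.87, Ldha 0.82) and 1 fell (Pdk1 −0.82) of 14. The microglia and hypoxia lists had medians of −0.06 and −0.18 while their tests pointed up. Extracellular matrix genes rose in 3 (Tnc 1.68, Mmp3 0.98, Plau 0.35) and fell in 1 of 14 (Mmp2 −0.95), circadian clock genes fell in 2 of 12 (Per3 −1.10, Dbp −0.98), and 1 of 10 mural cell genes fell (Col1a1 −1.23). Neutrophil genes rose in 1 of 10 (Mmp8 1.71), Schwann cell genes in 1 of 7 (Pou3f1 1.72) and excitatory neuron genes in 1 of 7 (Nts 0.83). Of the Hox lists, 1 of 8 rostral (Hoxb5 −0.49) and 1 of 11 caudal genes (Hoxb13 −0.48) fell. With limma over all genes 0 passed of 9 lymphocyte, 8 inhibitory neuron, 4 erythroid, 9 skeletal muscle and 12 cholesterol synthesis genes, in a comparison where 6238 of all genes had an unadjusted p under 0.05. Of the lists made after the data were seen, cardiac genes rose in 10 and fell in 2 of 40 (15 and 2 adjusted over the list alone, median 0.73, camera adjusted p = 1.96e-08, and 0.372 with an estimated correlation). None of 8 adipocyte or 8 sensory ganglion genes passed with limma; camera called the latter down (median −0.62, adjusted p = 0.0114, and 0.372 with an estimated correlation). The count of 2279 rests on a spread shared by all 6 groups: the SD of Il6 was 1.32 at 48 h and 0.07 in sham, and a fit of these 7 arrays alone called 142 genes. It was 801, 983 and 1048 without sham array 278, 279 or 280, 3665 without 48 h array 273, 5734 without array 274 and 4658 without arrays 271, 274 and 280. With array weights it was 6261, and among the brighter genes 1515.

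**Figure D2:**
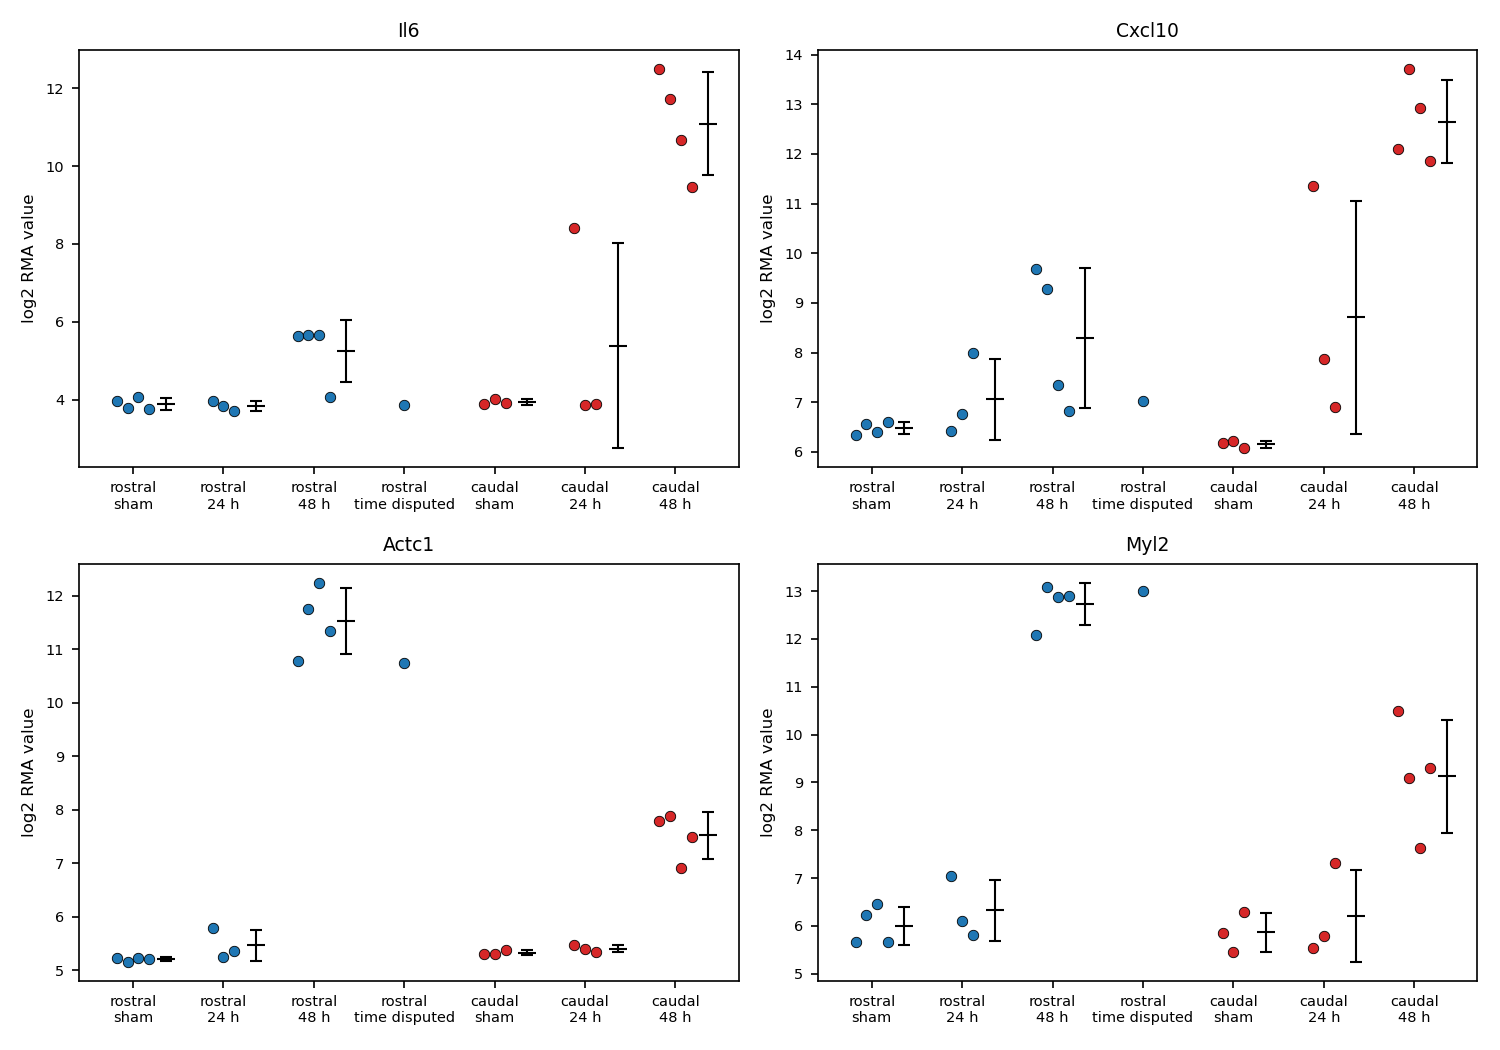
Log2 RMA signal of Il6, Cxcl10, Actc1 and Myl2 on each array (points), by region and time, with bars for the mean ± SD of a group. Il6 was 11.09 ± 1.32 in caudal cord at 48 h and 3.95 ± 0.07 in caudal sham, and Actc1 was 11.53 ± 0.62 in rostral cord at 48 h and 5.21 ± 0.03 in rostral sham.

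In caudal cord 24 h after clamping, 1 gene passed, against 293 with array weights. Lpl, the gene of lipoprotein lipase, went from 8.06 ± 0.08 (SD, n = 3) in sham to 9.66 ± 0.14 (SD, n = 3), a rise of 1.60 ± 0.21 (SE, adjusted p = 0.00903), and the arrays of the groups did not overlap. Several inflammatory transcripts had large values with a wide spread and did not pass: Ccl12 was 2.91 ± 0.77 above sham, Ccl3 2.91 ± 0.90 and Cxcl10 2.56 ± 0.86. Cxcl10 was 11.37 on array 281, 7.87 on 282 and 6.9 on the array labelled caudal 283, against 6.15 ± 0.07 (SD, n = 3) in sham. Il6 was 8.42, 3.87 and 3.89 on the same arrays. The next smallest p-values belonged to Ppm1j (−0.62 ± 0.13, unadjusted p = 0.000148) and Crygs (−0.86 ± 0.19, unadjusted p = 0.000299), and 529 genes had an unadjusted p under 0.05, fewer than the 910 expected by chance. That number assumes that the pooled spread holds in these groups, so the lower count does not show an absence of change.

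As lists, interferon response (median 0.80, camera adjusted p = 2.8e-07), chemokines (0.47, 6.47e-07) and cytokines (0.43, 0.000293) were called up in caudal cord at 24 h, together with monocytes (0.38, 0.00106), complement (0.29, 0.00475), reactive astrocytes (0.32, 0.0251), axon injury (0.18, 0.00503) and heat shock genes (0.09, 0.0206). Adjusted over the list alone, 4 chemokine, 3 monocyte, 2 complement and 1 heat shock gene passed. Neutrophil (−0.66), Schwann cell (−0.65), caudal Hox (−0.44) and mural cell genes (−0.33) were called down. None of these 12 calls held with an estimated correlation (adjusted p from 0.405 to 0.704). The upward calls rested most on array 281, whose interferon response mean was 9.38. It was 8.04 on array 282, 7.24 on the array labelled caudal 283 and 7.19 to 7.44 in sham. The array labelled rostral 283 had 7.98, against 7.25 and 7.26 on the other rostral 24 h arrays. Leaving out array 281 leaves array 282 and the array labelled caudal 283, so the losses below also reflect the doubt over that label. Without array 281 the chemokine call was kept (median 0.22, camera adjusted p = 0.0119) and the other 7 ended (interferon response 0.28, camera adjusted p = 0.0837; cytokines 0.11, 0.621; monocytes 0.22, 0.181; complement 0.25, 0.158; reactive astrocytes 0.16, 0.531; axon injury 0.16, 0.13; heat shock 0.07, 0.0894). The reactive astrocyte and heat shock calls also ended without sham array 279 (0.0659 for each). Without the array labelled caudal 283 all 4 downward calls ended (camera adjusted p = 0.0914 for neutrophils, 0.133 for Schwann cells, 0.2 for caudal Hox and 0.0887 for mural cell genes). The neutrophil call also ended without sham array 280 (0.234), and its direction turned without the 5 arrays that stood apart (0.838). The sensory ganglion list, made after the data were seen, was down by a median of −0.87, with 6 of 8 genes lower adjusted over the list alone (camera adjusted p = 2.28e-12, and 0.0168 with an estimated correlation), and by −0.78 without both arrays numbered 283 (adjusted p = 0.0178 with an estimated correlation). With an estimated correlation that call ended without sham array 278 (adjusted p = 0.0551) or 279 (0.0883). All 8 genes of that list were higher in caudal than in rostral sham adjusted over the list alone. A fall against the same sham arrays may thus come from the choice of the list. Lpl did not pass when any of the 5 arrays other than 283 was left out, with adjusted p-values from 0.0580 without sham array 280 to 0.106 without sham array 278.

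In rostral cord 24 h after clamping, limma called 0 genes against rostral sham (3 with array weights), and 141 had an unadjusted p under 0.05, against 910 expected by chance. The 910 again assumes that the pooled spread holds in these groups, so the low count does not show an absence of change. The smallest p-values belonged to Ankrd37, a hypoxia-induced gene (−0.74 ± 0.19, unadjusted p = 0.000809), Bsg (−0.37 ± 0.10, unadjusted p = 0.000993) and Lcn4 (0.34 ± 0.11, unadjusted p = 0.00509). Hypoxia (−0.08), cell cycle (−0.08), cholesterol synthesis (−0.09) and rostral Hox lists (−0.15) were called down, and Schwann cell (0.36) and caudal Hox lists (0.21) up, with camera adjusted p-values from 0.0107 to 0.0219. None held with an estimated correlation (adjusted p from 0.591 to 0.842). The hypoxia call ended without array 280, 281 or 282 (camera adjusted p = 0.0896, 0.0997 and 0.153), the cell cycle call without 281 or 282 (0.0655 and 0.153), the cholesterol synthesis call without 281 (0.0885) and the rostral Hox call without sham array 277 (0.0522). Without both arrays numbered 283, the Hox and Schwann cell calls ended (camera adjusted p = 0.563 for each Hox list and 0.955 for Schwann cells).

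In rostral cord 48 h after clamping, the largest rises were in genes of the heart muscle sarcomere and its metabolism. Myl2, a ventricular myosin light chain, went from 6.00 ± 0.40 (SD, n = 4) in sham to 12.73 ± 0.44 (SD, n = 4), a rise of 6.73 ± 0.47 (SE, adjusted p = 3.83e-08). Actc1, cardiac actin, rose by 6.32 ± 0.23 (adjusted p = 3.09e-12), myoglobin (Mb) by 6.09 ± 0.54, Myh6 by 5.83 ± 0.33, the atrial peptide gene Nppa by 5.29 ± 0.67, Tnnt2 by 5.17 ± 0.27, Tnni3 by 5.05 ± 0.39, Ttn by 4.95 ± 0.52, Pln by 4.83 ± 0.37 and Ckmt2 by 4.78 ± 0.32. Another probe set of Mb had the opposite sign, and the lowest probe sets of Myh6, Tnnt2 and Ttn rose by only 0.73, 0.50 and 0.09. Of 40 cardiac genes 31 rose (35 adjusted over the list alone, median 2.62, camera adjusted p = 4.71e-142, and 2.85e-05 with an estimated correlation); they were 17 of the 20 genes with the largest rise and 31 of the 86 that rose. The list was made after the data had been seen. Of the skeletal muscle list fixed beforehand, 1 of 9 genes rose (Ckm 2.60), and its call (median 1.06, camera adjusted p = 8.81e-06) ended with an estimated correlation (adjusted p = 0.189). That median came from array 273, where the list was raised by 4.15, against −0.14 to 0.12 on the other 3 arrays. Without it the median was 0.02 and the call ended (camera adjusted p = 0.0634). In all, 112 genes passed, 86 higher and 26 lower, and 64 and 3 of them changed at least 2-fold.

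Outside muscle genes, the fixed list with the smallest p in rostral cord at 48 h was cholesterol synthesis, which fell in 5 of 12 genes and in 10 adjusted over the list alone (median −0.43, camera adjusted p = 6.73e-20, and 0.000177 with an estimated correlation). Lss, lanosterol synthase, went from 8.86 ± 0.03 to 8.23 ± 0.13 (SD, n = 4 each), a change of −0.63 ± 0.07 (SE, adjusted p = 4.95e-05), with Dhcr7 (−0.73 ± 0.13), Mvd (−0.62 ± 0.11) and Fdft1 (−0.40). Glucocorticoid response genes rose in 4 of 10 and in 8 adjusted over the list alone (median 1.12, camera adjusted p = 8.15e-20, and 0.00564 with an estimated correlation): Plin4 (3.38 ± 0.58), Sult1a1 (2.05), Fkbp5 (1.86) and Pdk4 (1.84). Targets of p53 rose in 2 of 11 (5 adjusted over the list alone, median 0.36, camera adjusted p = 1.21e-06, and 0.039 with an estimated correlation), Cdkn1a by 1.82 ± 0.38 and Ccng1 by 0.73 ± 0.12. With the estimated correlation the p53 call ended without 48 h array 271, 272 or 273 or sham array 277, 279 or 280 (adjusted p = 0.069, 0.057, 0.0531, 0.0638, 0.0506 and 0.0548). The largest falls were in Serpinb1a (−1.45 ± 0.31), Opalin, an oligodendrocyte protein (−1.36 ± 0.30, and −0.09 for another probe set), the antigen-presenting H2-Aa (−1.33 ± 0.29, and −0.10 for another probe set), Pllp (−0.99 ± 0.18), Hoxd1 (−0.85 ± 0.17), Pltp (−0.83), Dhcr7, H2-Eb1 (−0.73 ± 0.16), Islr (−0.65) and Tmeff2 (−0.65, with another probe set of opposite sign). By the naming rule, for these falls and the 10 largest rises no 48 h array overlapped a sham one.

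Inflammatory lists were called up in rostral cord at 48 h, with few genes passing over all genes. Reactive astrocyte genes had 1 of 13 rising (Lcn2 3.06 ± 0.63) and 7 adjusted over the list alone (median 1.13), cytokine and NF-kappaB targets had 1 of 18 (Socs3 3.28 ± 0.73), and with limma 0 of 12 interferon, 15 chemokine, 15 monocyte and 10 complement genes passed, where 1287 of all genes had an unadjusted p under 0.05 (910 expected by chance). Camera adjusted p-values for these 6 lists ran from 4.24e-13 to 1.33e-05, and from 0.12 to 0.326 with an estimated correlation. Arrays 271 and 272 had the highest values: the interferon mean was 9.26 and 9.32 on them, 7.56 on 273 and 7.35 on 274, against 7.11 to 7.36 in sham, and the chemokine mean was 7.42, 7.33, 6.50 and 6.31, against 6.07 to 6.14. Cxcl10 was 1.81 above sham and did not pass (adjusted p = 0.522). Homeostatic microglia genes were called down (median −0.31, camera adjusted p = 1.89e-06, and 0.12 with an estimated correlation), and the pan-neuronal list was not called (median 0.01, camera adjusted p = 0.686). Of antigen presentation genes 2 of 13 fell, and the list had a median of 0.16 while its test pointed down (camera adjusted p = 0.665). Calls for oligodendrocytes, oligodendrocyte precursors, neutrophils and rostral Hox genes (down) and for immediate early, oxidative stress, unfolded protein, Schwann cell and homeostatic astrocyte genes (up) all ended with an estimated correlation (adjusted p from 0.169 to 0.556). At the preset correlation, the precursor call also ended without array 271, 272, 278 or 280, the unfolded protein call without 272, 274 or 277, and the astrocyte call without 273, 274 or 279 (camera adjusted p from 0.0614 to 0.134). The count of 112 was 58, 60 and 290 without 48 h array 272, 273 or 274, and 61, 66, 59 and 66 without sham array 277, 278, 279 or 280. It was 64 when the array of disputed time was counted as 48 h, where among others Serpinb1a, Opalin, H2-Aa, Pllp, Plin4, Fkbp5, Pdk4, Mvd and Cdkn1a lost their calls, and 52 without muscle and adipocyte genes. With array weights it was 1849, in a fit of these 8 arrays alone 454, and among the brighter genes 35.

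Caudal cord was compared between 48 h and 24 h after clamping to follow the response over time. Il6 was 11.09 ± 1.32 (SD, n = 4) at 48 h and 5.39 ± 2.62 (SD, n = 3) at 24 h, a difference of 5.69 ± 0.81 (SE, adjusted p = 0.00068). Cxcl2 was higher by 5.0 ± 0.62, Ptx3 by 4.50 (0.05 for another probe set), Ccl2 by 4.44, Cxcl10 by 3.94, Ccl3 by 3.82, Il1b by 3.81 ± 0.61, Chil3 by 3.73, Acod1 by 3.62 and Tslp by 3.58 ± 0.44. The amino acid transporter Slc38a5 (−1.90 ± 0.43), Gpr17 (−1.63 ± 0.28), Sox2ot (−1.51), Tek (−1.49 ± 0.30), Slco1c1 (−1.47), Gab1 (−1.38), Ddit4l (−1.37), Serpinb1a (−1.33), Gpr37 (−1.31) and Sgpp2 (−1.23) were lower. In these 20 genes the arrays of the groups did not overlap, as the naming rule required. In all, 771 genes were higher and 446 lower. Interferon response genes were higher in 12 of 12 (median 2.40), chemokines in 12 of 15 (14 adjusted over the list alone), cytokines in 14 of 18 (16 adjusted over the list alone), immediate early genes in 9 of 10 (9 adjusted over the list alone, median 1.58), p53 targets in 6 of 11 (8 adjusted over the list alone) and glucocorticoid response genes in 5 of 10 (9 adjusted over the list alone, median 1.15). Endothelial genes were lower in 4 of 13 (median −0.44) and oligodendrocyte precursor genes in 2 of 8 (median −0.53). Without array 271 the endothelial call ended (camera adjusted p = 0.0847). Of the 25 lists called, 17 up and 8 down, none held with an estimated correlation (adjusted p = 0.0597 for immediate early genes and p53 targets, and 0.0821 for chemokines). The count of 1217 was 0 in a fit of these 7 arrays alone (where 0 is a limma count), 256 without the array labelled caudal 283, 379 without array 282, 2252 without array 273 and 3722 without array 274. It was 184 without both arrays numbered 283, 4079 with array weights and 717 among the brighter genes.

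The largest differences between 48 h and 24 h in rostral cord were in cardiac genes: Myl2 was higher by 6.41 ± 0.51 (SE, n = 4 and 3, adjusted p = 3.71e-07), Actc1 by 6.06 ± 0.25, Myh6 by 5.72, Mb by 5.62, Nppa by 5.29, Tnnt2 by 5.23, Tnni3 by 4.81, Ttn by 4.77, Pln by 4.72 and Ckmt2 by 4.54, with another probe set of Mb of opposite sign. The arrays of the groups did not overlap for these genes, as the naming rule required. The lowest probe sets of Myh6, Tnnt2 and Ttn were higher by only 0.67, 0.51 and 0.04. Cardiac genes were 18 of the 20 largest rises and 31 of the 63 genes that were higher. The genes that were lower were Islr (−0.73 ± 0.15), Efemp1, an extracellular matrix protein (−0.67 ± 0.14), and Lss (−0.43 ± 0.08). Glucocorticoid response genes were higher in 3 of 10 (8 adjusted over the list alone, median 1.5; Plin4 3.12, Pdk4 1.93, Klf9 0.61), and cholesterol synthesis genes lower in 1 of 12 (8 adjusted over the list alone, median −0.41), and both held with an estimated correlation (adjusted p = 0.0036 and 0.00074). The call for p53 targets (1 of 11, Ccng1 0.76) ended with it (adjusted p = 0.0524). The count of 66 was 42 without the array labelled rostral 283, 175 without 48 h array 274, 20 with the array of disputed time counted as 24 h, and 21 without muscle and adipocyte genes. With array weights it was 1122, in a fit of these 7 arrays alone 40, and among the brighter genes 13.

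The regions were compared 24 h after clamping, and limma called 0 genes, with 57 at an unadjusted p under 0.05 (910 expected by chance if the pooled spread holds here). Hoxc10 was 8.73 ± 2.65 (SD, n = 3) on the arrays labelled caudal and 7.09 ± 2.65 (SD, n = 3) on those labelled rostral. Lpl was 9.66 ± 0.14 in caudal and 8.82 ± 0.49 in rostral cord, a difference of 0.85 ± 0.21 (unadjusted p = 0.000882), followed by Wdr27 (−0.41, unadjusted p = 0.00744) and Nphs1os (0.34, unadjusted p = 0.00883). Rostral Hox genes were lower as a list (median −0.36, camera adjusted p = 8.4e-14, and 0.0486 with an estimated correlation). Caudal Hox genes (0.38), interferon response genes (0.64) and chemokines (0.36) were among the lists called higher, and these calls ended with an estimated correlation (adjusted p = 0.111, 0.161 and 0.195). Without caudal array 281 the interferon and chemokine calls ended (camera adjusted p = 0.335 for each), and the rostral Hox call with an estimated correlation ended without caudal array 281 or 282 or rostral array 281 or 282 (adjusted p = 0.701, 0.153, 0.449 and 0.541). Each such omission leaves the array numbered 283 beside a lone array whose region genes match its label. These losses therefore also reflect the doubt over the labels of 283. Without both arrays numbered 283 the count was 24, and the caudal Hox, rostral Hox and interferon lists were called with an estimated correlation (medians 0.76, −0.72 and 1.28; adjusted p = 9.83e-07, 1.81e-06 and 0.0489).

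At 48 h the regions differed in 1767 genes, 1013 higher and 754 lower in caudal cord. Il6 was higher by 5.83 ± 0.75 (SE, n = 4 each, adjusted p = 0.000132), Ccl3 by 4.92, Cxcl2 by 4.87, Cxcl10 by 4.37, Ccl2 by 4.31, Ccl11 by 4.06, Il1b by 3.95 and S100a9, a neutrophil alarmin, by 3.83 ± 0.59. Hoxd10 (4.49 ± 0.97) and Hoxc10 (4.11 ± 0.89, 9.77 ± 0.46 against 5.66 ± 0.27) were higher as well. The 10 largest differences the other way were cardiac: Actc1 (−4.01 ± 0.23), Myh6 (−3.92), Pln (−3.77), Myl2 (−3.61), Ckmt2 (−3.60), Mb (−3.44), Tnnt2 (−3.31), Ankrd1 (−3.12), Ttn (−2.86) and Tnni3 (−2.82), with another probe set of Mb and of Ttn of opposite sign. By the naming rule, for these 20 genes no caudal array overlapped a rostral one. Chemokines were higher in caudal cord in 13 of 15 (14 adjusted over the list alone), interferon response genes in 11 of 12 (12 adjusted over the list alone), antigen presentation genes in 10 of 13 (11 adjusted over the list alone, median 0.92), neutrophil genes in 5 of 10 (9 adjusted over the list alone, median 1.66) and Schwann cell genes in 6 of 7 (median 1.29). Cholesterol synthesis genes were higher in 5 of 12 (7 adjusted over the list alone; Cyp51 0.71, Idi1 0.68, Fdft1 0.62), caudal Hox genes were higher in 7 of 11 and rostral Hox genes lower in 5 of 8. None of the 25 calls of fixed lists held with an estimated correlation (adjusted p = 0.0533 for antigen presentation, 0.0605 for cholesterol synthesis, 0.0762 for chemokines, 0.108 for interferon response and caudal Hox genes and 0.138 for rostral Hox genes). The count was 818 and 953 without rostral array 273 or 274, 3227 and 3801 without caudal array 273 or 274, 92 in a fit of these 8 arrays alone and 1060 among the brighter genes.

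Whether the clamp effect differed between regions was tested as a difference of effects, caudal minus rostral, each against its own sham. At 24 h limma called 0 genes (36 with array weights), and 337 had an unadjusted p under 0.05 (910 expected by chance if the pooled spread holds here). The smallest p-values belonged to Ppm1j (−0.76 ± 0.18, unadjusted p = 0.000447), Crygs (−1.11 ± 0.27, unadjusted p = 0.000552) and Lpl (1.15 ± 0.29, unadjusted p = 0.000903). The Schwann cell (−1.08) and caudal Hox lists (−0.61) were called lower and chemokines (0.47) and interferon response (0.63) higher. None of 10 such calls of fixed lists held with an estimated correlation (adjusted p = 0.263 for the lower pair and 0.771 for the higher pair). The sensory ganglion list, made after the data were seen, was lower by a median of −1.08 (camera adjusted p = 0.0106 with an estimated correlation). Its genes were high in caudal sham, so the choice of the list favours a negative difference. Without caudal array 281 the chemokine and interferon calls ended (camera adjusted p = 0.222 and 0.926), and without rostral array 281 the interferon call ended (0.107). At 48 h 102 genes differed, 74 with a positive and 28 with a negative difference. Il6 differed by 5.77 ± 1.11 (SE, adjusted p = 0.0179), Cxcl2 by 4.99 ± 0.85, Il1b by 4.13, Acod1 by 3.81, Tslp by 3.74 ± 0.60, Ccl7 by 3.65, Ccl4 by 3.54, Clec7a by 3.19, Gpr84 by 3.11 and Il1a by 3.08 ± 0.45. Fcrls, a microglial receptor gene, differed by 2.01 ± 0.23 (adjusted p = 0.000239), Atf3 by 2.87 ± 0.51 and C1qc by 1.39 ± 0.21. The largest negative differences were cardiac: Actc1 (−4.13 ± 0.34), Myh6 (−3.76), Pln (−3.74), Ckmt2 (−3.67), Mb (−3.59, with another probe set of opposite sign), Myl2 (−3.47), Tnnt2 (−3.45), Tnni3 (−3.01), Smpx (−2.97) and Tnnc1 (−2.82).

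As lists, the 48 h effect was larger in caudal cord for chemokines (3 of 15, and 13 adjusted over the list alone, median 2.64), cytokines (6 of 18, and 12 adjusted over the list alone, median 1.70), interferon response (1 of 12, and 11 adjusted over the list alone, median 2.28), monocytes (2 of 15, and 10 adjusted over the list alone, median 1.27), complement (2 of 10, and 4 adjusted over the list alone) and immediate early genes (2 of 10, and 9 adjusted over the list alone, median 1.22). Antigen presentation and cholesterol synthesis were called with a positive difference, but with limma 0 of 13 and 0 of 12 genes passed (7 and 4 adjusted over the list alone), where 2226 of all genes had an unadjusted p under 0.05. For cholesterol synthesis this came with a fall in rostral cord (median −0.43) and no call in caudal cord (median −0.12). Pan-neuronal (−0.43) and motor neuron lists (−0.39) were called lower. Without caudal array 271 the medians were −0.20 and −0.27, and the calls were kept (camera adjusted p = 0.000554 and 0.012). No call of a fixed list held with an estimated correlation (adjusted p = 0.0813 for chemokines, cytokines, antigen presentation, immediate early and cholesterol synthesis genes, 0.127 for monocytes and motor neurons, 0.135 for interferon response, 0.251 for complement and 0.361 for pan-neuronal genes), and the glucocorticoid list was not called (median −0.34, camera adjusted p = 0.182). Of the cardiac genes 19 of 40 had a negative difference (33 adjusted over the list alone, median −2.09, camera adjusted p = 3.4e-36, and 0.0169 with an estimated correlation, or 0.089 without caudal array 274). The cardiac list was made after the data had been seen, so its choice can favour a negative difference. The count of 102 was 213 and 822 without caudal 48 h array 271 or 274, 59 without rostral array 273, 42, 49 and 57 without sham caudal array 278, 279 or 280, and 64, 65 and 65 without sham rostral array 278, 279 or 280. It was 168 with the array of disputed time counted as 48 h, 1367 with array weights and 19 among the brighter genes.

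**Figure D3:**
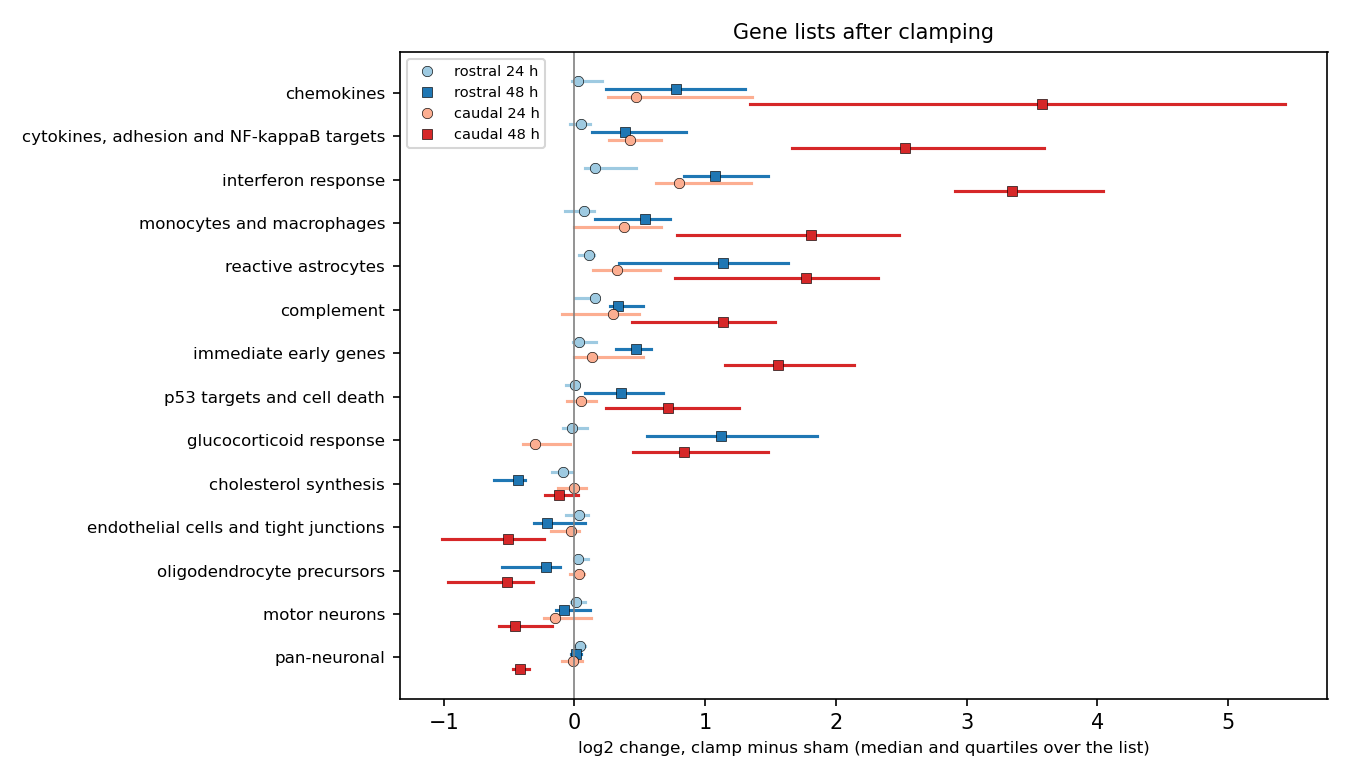
Median (points) and quartiles (bars) of the log2 change against sham over the members of 14 gene lists, in caudal and rostral cord at 24 h and 48 h. The chemokine median was 3.58 in caudal and 0.78 in rostral cord at 48 h, and 0.47 in caudal cord at 24 h.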

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

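Of the tests in this part, all on the cardiac genes, on the arrays numbered 283 and on array 271 were chosen after the result had been seen, except the neuron test of array 271; the counts over other splits of the arrays were planned. A sample was picked out when its gap to the nearest of its group of 4 was large for the group's range; 15 of 262 sets of values met this, and chance picks out about 1 in 20 groups, or 13.1 here.

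Heart muscle transcripts were raised on the rostral and on most caudal 48 h arrays (medians of 2.62 in rostral and 0.73 in caudal cord over 40 genes). Of these genes, 9 had a log2 signal above 7 in sham. On caudal array 273 the median rise was 0.13, within the range of the 24 h arrays. The caudal call of the list ended with an estimated correlation (camera adjusted p = 0.372). Skeletal muscle from around the spine is argued against, since the skeletal muscle list rose by under 0.5 on 3 of the 4 rostral arrays, and so is an ischaemic response largest below the clamp, since the median difference of effects, caudal minus rostral, was −2.09 (quartiles −3.00 to −0.82). The cardiac list was made after the data had been seen, so its choice can favour a negative difference and limits the latter test. Heart tissue or heart RNA in the samples stays open: the excess over sham ranked the 40 genes alike in rostral and caudal arrays (Spearman's rho 0.860 across genes, which are not independent replicates). Rostral array 276, of disputed time, also had a median cardiac rise of 2.76. The title numbers run in blocks by group, so an effect tied to their order cannot be told apart from the 48 h groups. How heart RNA could reach cord samples was not tested, and a cardiac programme induced in rostral cord cells was not tested either. Among the most abundant heart genes, Myl2 reached 12.73 and Actc1 11.53 in rostral cord at 48 h.

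Region genes went against the labels of both arrays numbered 283. On a scale from own region (0) to the other (1), loss of regional expression after clamping is argued against for the array labelled rostral 283 (0.633), since the other rostral 24 h arrays had a median of 0.00881. It is also argued against for the Hox genes of the array labelled caudal 283 (1.02 on the caudal list), where the other caudal 24 h arrays had a median of 0.0679. For its other region genes (0.885) it cannot be told apart, since those arrays had a median of 0.350. The region genes were chosen for their difference between the sham arrays that set the scale. Arrays outside sham can therefore fall short by that choice alone, and 0.350 does not show a loss of regional expression. An exchange of the region labels may account for the pattern, since 80.3% of 61 region genes lay nearer the other region on both arrays. The value of the array labelled rostral 283 (0.633) falls short of 1, but so do those of caudal 24 h arrays 281 and 282. From rostral (0) to caudal (1), these lay at 0.787 and 0.548. On the Hox lists the array labelled rostral 283 lay at 0.874 (caudal list) and 0.969 (rostral list). The shortfall alone thus does not point to a mixed sample, which was not tested and is not excluded. No label was changed, and a biological difference of these samples was not tested.

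The caudal 48 h array 271 stood apart. Degraded RNA with loss of 5-prime signal is argued against as the cause of its low standard deviation (2.05), since arrays 274 and 280, with larger losses on the Gapdh control (−1.05 and −0.68, against −0.21 on 271), had 2.22 and 2.24, within the range of the other arrays (2.21 to 2.27). Compressed signal over the whole array fits a slope of −0.149 of its deviations on brightness, against 0.02 to 0.04 for the other 3 arrays of the group. A loss of neurons in this sample may add to it, since the pan-neuronal list lay at percentile 2.99 of 10000 lists matched on brightness, but the endothelial list was also low (percentile 7.38; astrocytes, microglia and oligodendrocytes 34.6 to 58.3). These explanations do not exclude each other, and a larger injury in this sample was not tested.

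On array 271 the homeostatic astrocyte mean was 10.92 against 11.56 to 11.67 on the other 3 caudal 48 h arrays, the inhibitory neuron mean 8.88, Dlgap2 4.50 and Clec7a 12.18. Caudal 48 h array 274 had Depdc7 at 6.82 and Gpr84 at 8.35, against 5.09 to 5.15 and 10.15 to 10.37 on the others. Among rostral 48 h arrays, 273 had a skeletal muscle mean of 9.76 and Islr at 8.66, 274 a p53 target mean of 8.04 and Il6 at 4.06, and 272 a sensory ganglion mean of 6.32. In rostral sham, array 280 had a complement mean of 7.99, array 277 Pmp2 at 5.01 and Sbspon at 5.06, and array 279 Ccl7 at 5.85. Array 276, in no group, had a cardiac mean of 8.79 against 5.95 to 6.00 in rostral sham.

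The clamp effect at 48 h differed between regions in 102 genes, tested as a difference of effects. The named genes with the larger effect in caudal cord were Il6 (5.77), Cxcl2 (4.99), Il1b (4.13), Acod1 (3.81), Tslp (3.74), Ccl7 (3.65), Ccl4 (3.54), Clec7a (3.19), Gpr84 (3.11) and Il1a (3.08). Those with the larger effect in rostral cord were Actc1 (−4.13), Myh6 (−3.76), Pln (−3.74), Ckmt2 (−3.67), Mb (−3.59), Myl2 (−3.47), Tnnt2 (−3.45), Tnni3 (−3.01), Smpx (−2.97) and Tnnc1 (−2.82).

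Other splits of the same arrays into groups of the same sizes were counted for each number of genes. The share of splits that gave as many genes was under 0.05 for rostral cord at 48 h against sham (1 of 35, 112 genes, highest other 0). It was also under 0.05 for the regions in sham (1 of 35, 61, highest other 0) and at 48 h (1 of 35, 1767, highest other 1169). These shares were not adjusted over the comparisons and do not exclude chance on their own. The splits ignored the numbers in the titles, so for the regions they would not be valid if the numbers mark pairs. The share was not under 0.05 for caudal cord at 48 h against sham (3 of 35, 2279, highest other 6015), caudal 48 h against 24 h (3 of 35, 1217, highest other 4206), rostral 48 h against 24 h (2 of 35, 66, highest other 171) and the effect difference at 48 h (2 of 35, 102, highest other 632). In these 4, every split that gave more genes moved only array 273 or 274 to the other group and kept the other 3 arrays at 48 h apart from it. Such splits still hold most of the contrast and point to a structure of the samples, so the count of splits alone does not weigh against a clamp effect there. For rostral 24 h against sham the real count was 0, so every split had to give as many (35 of 35; highest other 0) and nothing is shown. The splits were too few for a share under 0.05 in caudal cord at 24 h against sham (1 of 10; 1, highest other 0), the regions at 24 h (10 of 10; 0, highest other 35, from the split that exchanges the arrays numbered 283) and the effect difference at 24 h (10 of 10; 0, highest other 0).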

How the results depend on the processing

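The alternatives that leave out named arrays together, leave out muscle and adipocyte genes, or use cameraPR without a block, and each array left out for the lists, were chosen after seeing the data. Array weights gave 293, 6261, 3, 1849, 4079, 1122, 1257, 36 and 1367 genes for caudal 24 h, caudal 48 h, rostral 24 h and rostral 48 h against sham, caudal and rostral 48 h against 24 h, the regions in sham, and the effect difference at 24 h and 48 h. Only the groups compared gave 142 (caudal 48 h), 454 (rostral 48 h), 0 (caudal over time, by limma), 40 (rostral over time), 832 (sham regions) and 92 (regions at 48 h). Every probe set as a feature gave 3859 for caudal 48 h, 1931 for caudal over time and 2821 for the regions at 48 h. The brighter genes, with fewer genes tested, gave 1515, 35, 717, 13, 0, 1060 and 19 for caudal 48 h, rostral 48 h, caudal and rostral over time, sham regions, regions at 48 h and the effect difference at 48 h. A change of at least 2-fold, a stricter rule by construction, gave 543 (caudal 48 h), 67 (rostral 48 h), 427 (caudal over time) and 437 (regions at 48 h). The number in the title was shared by arrays whose residuals correlated by −0.450 to 0.534 (above 0.1 in 6 of 10 pairs; 13 of 20 arrays correlated best with their own number), with the negative values in the 24 h pairs, where the labels of 283 are in doubt. Without both arrays numbered 283, each 24 h group holds 2 arrays, so numbers 281 and 282 share 1 value by construction (0.000909). The other numbers ran from 0.0863 (280) to 0.534 (274), so whether the numbers mark pairs stays open. As a random block (consensus correlation 0.138) it gave 189 for the effect difference at 48 h, and as a fixed block 177, and 0 for sham regions; with cameraPR, the random block gave 23 lists against 24 there. Array 276 as 24 h gave 20 for rostral over time and 3 lists for rostral 24 h, and as 48 h it gave 64 for rostral 48 h and 168 for the effect difference at 48 h. Without both arrays numbered 283 the counts were 2 (caudal 24 h), 184 (caudal over time), 41 (rostral over time), 98 (sham regions) and 24 (regions at 24 h). Without caudal arrays 271, 274 and 280 they were 0, 4658, 887, 3746, 405, 109, 3202 and 887 for caudal 24 h, caudal 48 h, rostral 48 h, caudal and rostral over time, sham regions, regions at 48 h and the effect difference at 48 h; without all 5 arrays they were 2, 4528, 839, 2572, 105, 189, 3109 and 789, and 60 for the regions at 24 h. Without muscle and adipocyte genes they were 52 for rostral 48 h and 21 for rostral over time. Apart from the fewer genes, fewer samples and stricter rule named, the cause was not tested. Leaving out 1 array at a time gave 0 to 1 (caudal 24 h), 801 to 5734 (caudal 48 h), 0 (rostral 24 h, regions at 24 h and effect difference at 24 h), 58 to 290 (rostral 48 h), 256 to 3722 (caudal over time), 42 to 175 (rostral over time), 0 to 25 (sham regions), 818 to 3801 (regions at 48 h) and 42 to 822 (effect difference at 48 h). With an estimated correlation 3 of the lists fixed beforehand were called for rostral 48 h and 2 for rostral over time. For sham regions 4 of them were called, for the regions at 24 h 1, and elsewhere 0. Lists made after the data had been seen are not in these counts. Of those, sensory ganglia were called for caudal 24 h and the effect difference at 24 h. Cardiac genes were called for the regions and the effect difference at 48 h, among others. Directional fry called 0 lists for both 24 h comparisons with sham, the regions at 24 h and the effect difference at 24 h, 3 for rostral 48 h and rostral over time, 4 for sham regions and 13 for the effect difference at 48 h; mixed fry called 0 in the same 4 comparisons, 3, 3, 1 and 11. The region check found 3 arrays nearer the other region, and 2 with arrays centred on their median. Hoxd13 in sham (−0.08) ranged from −0.15 to 0.00285 over arrays left out in turn and turned positive without sham caudal array 280, alone or with others (0.00285). Without all 5 arrays the direction turned for 6 lists: neutrophils in caudal cord at 24 h (adjusted p = 0.838), rostral and caudal Hox genes in rostral cord at 24 h (0.516 and 0.512), caudal Hox genes in rostral cord over time (0.985), skeletal muscle between regions at 24 h (0.967) and rostral Hox genes in the effect difference at 24 h (0.0693). Of the other single results, named genes stayed on their side of the threshold 8087 times, lost the call 1292 times and gained it 48 times, and lists kept it 1168 times and lost it 481 times. No scaling moved the median of all genes by over 0.1. Changes of dim genes are limited by signal over background, and counts by the number of arrays.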

Other observations

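From 24 h to 48 h in caudal cord, monocyte genes were higher in 8 of 15 (13 adjusted over the list alone, median 1.24, camera adjusted p = 9.3e-12, and 0.0821 with an estimated correlation), reactive astrocyte genes in 8 of 13 (12 adjusted over the list alone, median 1.44, 7.51e-09, and 0.123), cell cycle genes in 7 of 17 (10 adjusted over the list alone, median 0.42, 4.72e-08, and 0.0821) and Schwann cell genes in 3 of 7 (4 adjusted over the list alone, median 0.91, 0.0009, and 0.129). Between regions at 48 h, the motor neuron genes Slc5a7, the choline transporter (−1.14), and Slc18a3, the vesicular acetylcholine transporter (−1.11), were lower in caudal cord. They were the 2 of 10 motor neuron genes that passed, and the list was not called (median −0.16, camera adjusted p = 0.143). Immediate early genes were higher in 9 of 10 (10 adjusted over the list alone, median 1.49, camera adjusted p = 1.38e-10, and 0.0605 with an estimated correlation).

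The array of disputed time, rostral 276, had a median rise of 2.76 in the cardiac list over rostral sham. Its pan-neuronal mean was 12.44 against 12.51 to 12.63 in rostral sham, its cholesterol synthesis mean 10.28 against 10.41 to 10.48, its glucocorticoid response mean 9.56 against 9.51 to 9.72 and its chemokine mean 6.23 against 6.07 to 6.14.

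The skeletal muscle list was raised by a median of 4.15 on rostral 48 h array 273 and 1.23 on the array labelled caudal 283, which also had adipocyte genes raised by 0.85, and adipocyte genes were raised by 0.59 on caudal array 271. Over all 22 arrays Xist lay between 11.60 and 12.70, and the Y-linked genes Eif2s3y, Kdm5d and Uty lay between 3.35 and 3.78, 4.41 and 5.15, and 4.05 and 4.69.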
